A study of Bos taurus with 8 samples.

How the data were processed

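RNA of neutrophils from jugular vein blood of Holstein Friesian cows was hybridised to bovine Agilent arrays in a single colour (Cy3), with 4 arrays of samples taken 14 days before the expected calving and 4 arrays of samples taken 7 days after calving. The series text names 3 cows, fewer than the 4 arrays of each time point, and no label ties an array to a cow. At least 2 arrays of each time point therefore come from the same cow or from material that is not 1 sample per cow, and no cow term could be fitted. Sharing a cow within a time point makes p-values over arrays too small. Cows shared across the time points, also not modelled, would make them too large, so the net direction of the error is unknown. RNA was extracted with TRIzol, per the labels' protocols.

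The deposited scanner files hold spot intensity values written by Agilent Feature Extraction. The submitters' processing notes name version 9.1, while the file headers name version 10.10.1.1, protocol GE1_1010_Sep10 and a probe annotation on build UMD_3.1. Per the file headers, the background-subtracted intensity and the processed intensity are given side by side. On 7 arrays both were the same among spots well above background (highest relative difference 4.95e-06). On before-calving replicate 3 the software had also applied a multiplicative surface correction (root mean square of its fit 1.83), and the ratio of processed to subtracted intensity there had a 1st percentile of 0.118, a median of 0.614 and a 99th percentile of 71.3. The deposited series matrix holds log2 values of the same arrays. Set against the scanner values (lowest correlation 0.999), its 43711 rows matched log2 intensity with values under 1 set to 1, less the 75th percentile of each array and centred on each probe's median, so differences between arrays run in the same direction as in the scanner files. These steps were read from the values, and no header states them. The column medians of the series matrix lay between -0.128 and 0.0289, except at -2.61 on before-calving replicate 3.

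Each array carried 43653 probes on 43803 spots, besides 1417 control spots, which were left out with the spots flagged as outliers. Spots of a probe were averaged. Probe accessions were named through a table of RefSeq genes of assembly ARS-UCD2.0, used for names alone, which gave a symbol to 26832 probes (12639 symbols) and none to 16821. A gene with several probes was represented by its brightest probe past the filter, and for genes named by the rule below the values of other probes past the filter are given where they differ by over 0.5 on the log2 scale. A feature was tested where its probe was well above background on all arrays of at least 1 time point, a call of the extraction software that needed over 0.5 of the probe's spots.

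For the comparison of all 8 arrays, log2 processed intensity was scaled by each array's 75th percentile and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold adjusted p of 0.05). The percentile was taken over the 118 probes well above background on all 8 arrays because under 11% of probes were detected on any array. The plan fixed before the data were examined had named all probes for this step, and that scaling was run as an alternative.

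The second fit was chosen after seeing the data. It used the 6 arrays with over 2000 probes well above background, 3 of each time point, and the background-subtracted intensity, which lacks the surface correction. Intensities were scaled by the 75th percentile over the 1111 probes detected on all 6 arrays, raised to a common floor at log2 -3.54 and put on the log2 scale. The floor is the highest, over the 6 arrays, of the lowest scaled signal well above background. Several other combinations of arrays, signal and floor were fitted before this one was settled, and not all of their counts are given, so its count of genes is not that of a planned test. A difference with a time point at the floor is a lower limit. For genes not well above background on any array of the dimmer time point, "at least N-fold" is the fold of the fitted difference, measured from the common floor. The fit of 8 arrays added no floor, but most spots lay at the array's lowest processed value, except on before-calving replicate 3. There "at least N-fold" sets the brighter time point's mean against, on each array, the higher of the lowest processed signal well above background and the probe's own.

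The 21 gene lists and 9 cell type marker lists were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation), which sets a list's genes against the other tested features. A list called lower by camera can therefore hold genes that rose less than the rest. They were also tested with fry, which asks whether a list's genes move on balance in a single direction. The rule for named genes, also fixed then, took the 8 largest differences each way among features past the threshold with a gene symbol and no overlap between the time points, or, where none passed, the up to 8 smallest p-values each way among such non-overlapping features. It added for each list up to 3 members past the threshold, or the 2 smallest p-values where fewer than 2 passed, and 12 fixed neutrophil genes where measured. MMP9, BPI, CHI3L1 and, on the 6 arrays, S100A12 were named after their values were seen. Some genes that the rule names are not reported here, although they stayed in the fits and list tests.

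The alternatives covered background correction (normexp with offset 50, on median spot signals because mean signals were not used here), normalization, the filter on dim probes, flagged spots, the probes of a gene, the model and each array left out in turn. Both fits were tested on simulated data made from the real means and spreads. For the 8 arrays (434 features, 100 changed, 20 repeats) 0.735% of features changed by 1 on the log2 scale were called, 6.21% of those changed by 2 and 28.0% of those changed by 3, against 0.120% of unchanged features. For the 6 brighter arrays (1928 features, 200 changed) the shares were 27.7%, 77.8% and 91.4%, against 0.388% of unchanged features. Simulated lists of 10 genes shifted by 1 were called in 41% of draws on 8 arrays and in 100% on 6, and unshifted lists in 0% and 4%. The simulated noise was drawn independently for each gene. None of these shares therefore covers correlation between genes or shifts of a whole array, and no real list stayed called with an estimated correlation. The number of arrays limits the precision of every value.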

Results

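The data compare blood neutrophils of periparturient dairy cows at 2 times, 14 days before the expected calving and 7 days after calving, with 4 arrays at each time. Signal was low on all arrays. The share of probes well above background ranged from 0.893% to 10.3%, or 4177, 2380, 4493 and 780 probes on the before-calving replicates 1 to 4 and 2225, 2290, 2759 and 390 on the after-calving replicates. After-calving replicate 4 correlated with the 6 brighter arrays at -0.03 to 0.19 over 1111 probes, and before-calving replicate 4 at 0.59 to 0.72, while the 6 brighter arrays correlated among themselves at 0.69 to 0.95 (across probes, which are not independent). The 4 arrays of a time point shared a slide and a scan, and none of the 2 slides held both times, so slide and time point cannot be told apart in any comparison.

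**Figure D1:**
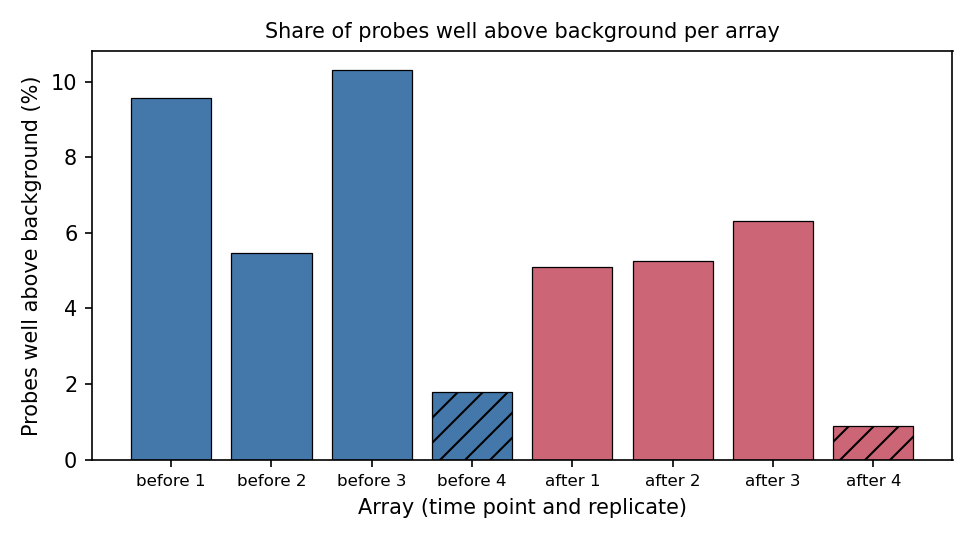
Percent of probes well above background (vertical axis) on each of the 8 arrays, before calving in blue and after calving in red. The hatched bars are the replicates numbered 4, at 1.79% before and 0.893% after calving, and the other 6 arrays lie between 5.10% and 10.3%.

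Over all 8 arrays no gene passed the threshold between the times, and the class II major histocompatibility genes, which present antigen to T cells, were lower after calving by a list test with a preset correlation (adjusted p = 6.64e-05), a call that was lost with an estimated correlation (adjusted p = 0.0931) and by fry (adjusted p = 0.118). The smallest adjusted p of a gene (0.360) belonged to the class II gene BOLA-DQA5, which was not well above background on any array after calving, at a level at least 3.29-fold below that before. UPP1, a uridine phosphorylase, was at a log2 difference after minus before of 2.33 (SE 1.08) and SREBF2, a regulator of sterol synthesis, at 0.80 (SE 1.04), neither past the threshold.

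With limma, 0 of 452 features passed at an adjusted p of 0.05, 6 had an unadjusted p under 0.05 (4 higher and 2 lower after calving), and the limma variants with trend and robust and with a random block also called 0. The median SD within a time point was 1.57 on the log2 scale. Of the 2 lists with enough measured genes, the class II list, called by camera with the preset correlation alone, had 5 members, all with negative values (median -1.24). Within it CTSS, which codes for the protease cathepsin S, was at -1.63, and 1 member fell when adjusted over the list alone. The 35 ribosomal protein genes had a median of -0.39 (adjusted p = 0.415), with RPLP2 at 1.14 and RPS3A at -1.09 (-0.47 on its other probe). By camera, against the other features, this list was called lower with normexp (adjusted p = 0.00988) but higher with array weights (adjusted p = 0.00451). By fry with normexp it did not pass (adjusted p = 0.673). On after-calving replicate 4, CTSS, BOLA-DQA5 and RPS3A lay at that array's lowest processed value (scaled log2 -4.09).

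Values of the other list members on 8 arrays did not pass the threshold. S100A12, a member of the granule protein list, was at 1.74 and the integrin gene ITGB2 at 0.91, against -0.56 on its other probe. Negative values were found for CD247, a chain of the T cell receptor complex (-2.43), ATF4 (-1.75), S100A4 (-1.21, and -0.53 on its other probe), NFKBIA (-0.96), CSF1R (-0.92), LYN (-0.91), KLF6 (-0.79), FOSB (-0.69), ATP5F1A (-0.64), COX6A1 (-0.56), CD4 (-0.45) and GPX1 (-0.28). On after-calving replicate 4 these genes, ATP5F1A and CD4 apart, lay at that array's lowest processed value (scaled log2 -4.09), as did 79.4% of its spots. Their values there are not measured levels. Without that array GPX1 was at 0.66, and the other negative genes stayed negative. HSPB1 also lay at that lowest value. NKG7 was at 0.30, ANXA1 at 0.20 and HSPB1 at 0.10. The 12 fixed neutrophil genes were too dim to be tested on 8 arrays. Array weights estimated by limma gave 11 features past the threshold, and 1 passed without after-calving replicate 4. Where arrays of a time point share a cow, p-values over arrays are too small, and where the times share cows they are too large. The net direction of the error is unknown.

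On the 6 brighter arrays, a choice made after seeing the data, 5 of 10 tested genes of the granule protein list rose after calving, while 2 of 4 T cell markers and 1 of 6 genes each of class II antigen presentation and of the interferon response fell. LTF, which codes for the iron-binding granule protein lactoferrin, rose at least 10.2-fold (log2 difference 3.35, SE 0.29; 1.80 on its other probe), and HP, which codes for haptoglobin, a binder of free haemoglobin, rose by 3.50 (SE 0.15). ALOX15, a lipoxygenase abundant in eosinophils, fell by 3.04 (SE 0.14), ISG15, a ubiquitin-like protein induced by interferon, by 2.86 (SE 0.38) and CD247 by 2.66 (SE 0.36). In all, 92 of 1952 features passed the threshold, 35 higher and 57 lower after calving (n = 3 arrays at each time). The balance moved with the scaling, the signal and the arrays, to 45 higher and 2 lower with normexp, 12 higher and 77 lower with scaling over all probes, and 5 higher and 0 lower in the series matrix, with the median of all features at 0.66, -0.58 and 1.02 in turn, against -0.07 here. It was 33 higher and 13 lower without after-calving replicate 1, and 69 higher and 66 lower with processed signal and before-calving replicates 1 and 2 only.

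The count rests strongly on single arrays and on the signal used. It was 6 without after-calving replicate 2, 4 without after-calving replicate 3 and 46 without after-calving replicate 1. It was 7 with before-calving replicate 4 added, which also raises the common floor, and 18 with the processed signal. Where arrays of a time point share a cow, p-values over arrays are too small, and where the times share cows they are too large. Here too the net direction is unknown. In 30 of the 92 features all arrays of a time point lay at the floor, where the spread is 0 by construction, and a separate fit of the 1000 features well above background on all 6 arrays called 44, of which 26 were among the 92. At an unadjusted p under 0.05 there were 400 features. Among those 1000 features, where the filter does not favour either time, the times did not overlap in 267 (26.7%), against 10% by chance and 3.5% to 15.3% in the 9 other splits of these arrays.

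**Figure D2:**
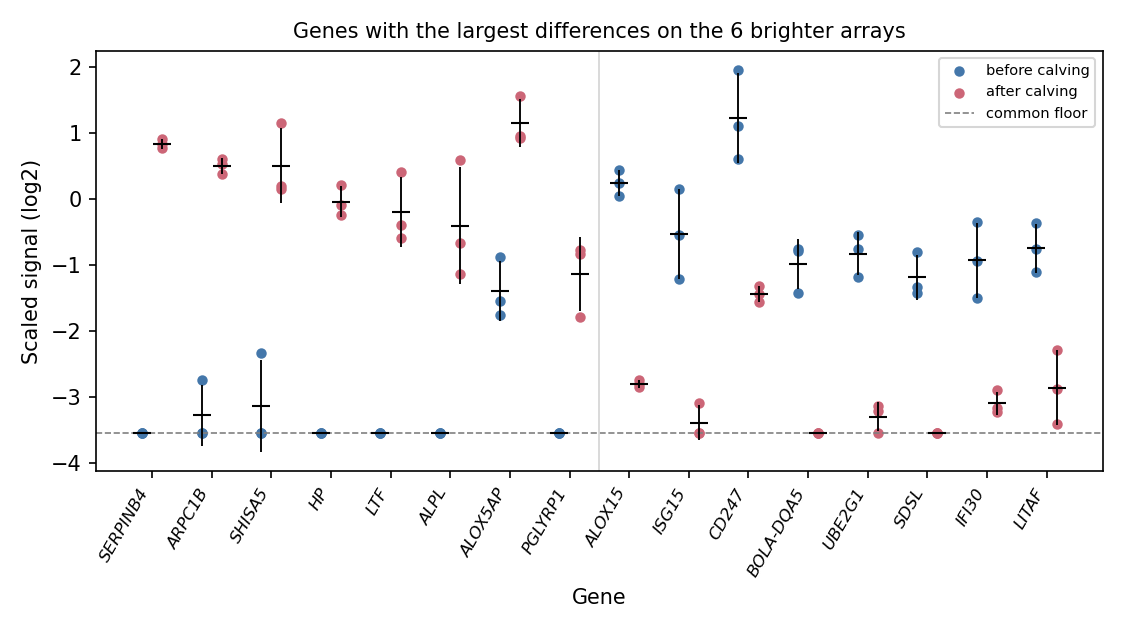
Scaled signal (log2, vertical axis) of the 8 genes with the largest rise and the 8 with the largest fall on the 6 brighter arrays, as points per array before (blue) and after calving (red), with mean and SD in black and the common floor at -3.54 as a dashed line. SERPINB4, HP, LTF, ALPL and PGLYRP1 lie at the floor on all 3 arrays before calving, and BOLA-DQA5 and SDSL on all 3 after calving.

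SERPINB4, a serpin protease inhibitor whose probe may also bind related serpins, rose at least 20.8-fold (log2 4.38, SE 0.11, adjusted p = 0.000192), with a log2 difference of 1.86 on its other probe. ARPC1B, a subunit of the actin-nucleating Arp2/3 complex, rose by 3.78 (SE 0.26), SHISA5 by 3.64 (SE 0.47) and ALPL, an alkaline phosphatase, at least 8.81-fold (log2 3.14). ALOX5AP, needed for leukotriene synthesis, rose by 2.54 (SE 0.31), while the other tested member of the eicosanoid list, TBXAS1, was at 0.32 and did not pass.

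Of the 10 genes tested from the granule protein list, 5 rose and none fell, and 6 rose when adjusted over the list alone. Besides LTF and HP, PGLYRP1, a peptidoglycan-binding protein, rose at least 5.31-fold (log2 2.41), MMP9, a gelatinase, at least 4.33-fold (log2 2.11) and S100A12, a calcium-binding protein abundant in neutrophils, by 2.27 (SE 0.32), with 0.54 on its other probe. S100A9 was at 0.69 and did not pass, nor did the 2 members with negative values, BPI at -0.019 and CHI3L1 at -0.67. The list was higher by camera (median 1.80, adjusted p = 3.57e-06), with adjusted p = 0.147 with an estimated correlation. LTF, HP, PGLYRP1 and S100A9 lay at the floor on all arrays before calving and passed the filter through the after-calving arrays. Their values could therefore not be negative, and the filter favours a rise of this list. Of the 4 immature granulocyte markers tested LTF rose, while CEBPE, at -0.31, and again BPI and CHI3L1 had negative values without passing (median of the 4 -0.17).

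Of the 4 T cell markers tested, CD247 and CD3E, which code for chains of the T cell receptor complex, fell, CD3E at least 4.08-fold (log2 -2.03, SE 0.14). Of the natural killer markers GNLY fell by 1.67, and NKG7 was at -0.56 without passing. The single monocyte marker tested, CSF1R, fell by 1.64 (SE 0.26), and was at 0.018 in the series matrix, where the median of all features was 1.02. ALOX15 was the single eosinophil marker tested. The B cell marker CD79A, at -0.44 (SE 0.49), did not pass, nor did the haemoglobin gene HBA, at 1.80 (SE 0.68). No basophil or platelet marker was bright enough to be tested.

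Of 6 class II genes tested BOLA-DQA5 fell (at least 5.88-fold, log2 -2.56) and 4 fell when adjusted over the list alone, while CTSS was at -2.08 (adjusted p = 0.0558), with -0.99 on its other probe. BOLA genes resemble each other and probes may bind several. The list was lower by camera (median -1.33, adjusted p = 0.00400), with adjusted p = 0.147 with an estimated correlation. The T cell markers CD247 and CD3E fell on the same arrays. The interferon-stimulated list was lower too (6 members, all negative, median -0.84, adjusted p = 0.0213), with adjusted p = 0.365 with an estimated correlation. In it ISG15 fell, 2 fell when adjusted over the list alone, and XAF1 was at -0.97. Of 10 heat shock and endoplasmic reticulum stress genes HSPA8, a constitutive chaperone, fell by 0.90 (SE 0.15; -0.45 on its other probe), 4 fell when adjusted over the list alone, and ATF4 was at -1.22. This list was lower by camera (median -0.80, adjusted p = 0.00797), with adjusted p = 0.289 with an estimated correlation. By fry the same 4 lists were called.

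The largest falls outside these groups were in UBE2G1, a ubiquitin-conjugating enzyme (-2.47, SE 0.22), SDSL (at least 5.11-fold, log2 -2.35), IFI30, a lysosomal thiol reductase induced by interferon (-2.16, SE 0.32), and LITAF (-2.11, SE 0.36). With before-calving replicate 4 added, PGLYRP1 was at 0.015, BOLA-DQA5 at -0.10, IFI30 at -0.042 and LITAF at -0.037, none past the threshold. That array also raises the common floor, which alone shrinks differences of genes with signal near or under it. These values therefore do not show that the differences vanish. GNLY was at -0.00067 with normexp, where the median of all features was 0.66. PRDX5, an antioxidant peroxiredoxin, rose by 1.84 (SE 0.15), and GLRX was at -0.39. The death receptor gene FAS fell by 1.03 (SE 0.15) and was at 0.18 with normexp, where the median of all features was 0.66. ZFP36L2, an RNA-binding regulator of transcript decay, fell by 1.11 (SE 0.20) and was at 0.63 in the series matrix, again beside a median of 1.02, and its other probe was at -0.37.

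Other lists did not pass. Pathogen recognition had a median of 0.46 over 5 genes (adjusted p = 0.274), with TLR6 at 2.41 (0.23 on its other probe), TREM1 at 1.52 and TLR2 at 0.46. TLR6 and TREM1 lay at the floor on before-calving replicate 2 alone, and stayed positive with each array left out (lowest 1.61 and 0.72). Glycolysis had a median of 0.48 over 6 (adjusted p = 0.274), with LDHB at 0.77 (0.06 and 0.16 on its other probes) and TPI1 at -0.65. Oxidative phosphorylation was at -0.17 over 21 (adjusted p = 0.808), with UQCRB at -0.72 and ATP5F1A at -0.89. Fc and complement receptor signalling was at -0.29 over 6 (adjusted p = 0.717), with LYN at -0.79 and LAMP2 at -0.37. The 49 ribosomal protein genes had a median of -0.06 and a mean of 0.27 (adjusted p = 0.905), with RPL10A at 2.32 and RPS15A at -0.86, against 1.35 on the other RPS15A probe. By camera, against the other features, the ribosomal protein list was called lower with normexp (adjusted p = 0.00102) and with no filter (adjusted p = 5.80e-17). By fry it was higher with normexp (adjusted p = 0.521) and lower with no filter (adjusted p = 0.935), neither past the threshold. It was called higher by camera with before-calving replicate 4 added (adjusted p = 0.0149), which also called glycolysis higher (adjusted p = 0.0149). That array also raises the common floor. Antioxidant defence had a median of -0.23 and a mean of 0.27 over 8 (adjusted p = 0.717).

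Among lists with fewer than 5 tested genes, no member other than those already named passed. In the adhesion and migration list CXCR1 was at -1.27 (adjusted p = 0.0629), CXCR2 at -0.08, ITGB2 at -0.24 and SELPLG at -0.13. NFKBIA was at -1.31 and IL1B at -0.57. VAV1 was at 1.47 and RAC1 at 0.62, and DUSP1 at -0.37. MCL1 was at 0.35 and BIRC3 at -1.13 (0.0098 on its other probe), and BNIP3L at -0.45. HADHA was at -0.57 and ACADVL at 0.44. KLF6 was at -1.31 and FOSB at -0.70, and S100A4 at -1.23 and S100A11 at 1.62. VAV1, RAC1, MCL1, ACADVL and S100A11 lay at the floor on before-calving replicate 2 alone, which correlated with the other 5 brighter arrays at 0.687 to 0.787. Without that array RAC1 (-0.14), MCL1 (-0.82) and ACADVL (-0.035) were negative. VAV1 and S100A11 stayed positive with each array left out (lowest 0.64 and 0.58). No cell cycle gene was tested. MPO, S100A8, CXCL8, TLR4, NR3C1 and FKBP5 were too dim to be tested on either set of arrays.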

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

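The tests of explanations in this part were chosen after the results were seen, except the splits of the 8 arrays on list counts, and the choice of the 6 brighter arrays was itself made after seeing the data. Of 54 groups of 4 arrays examined, 4 held an array far from the other 3, and chance flags about 1 in 20. In the before-calving group 0.00228% of spots of replicate 3 lay at the array's lowest processed value, against 73.4% to 80.4% on the other 3, and the root mean square of its surface correction was 1.83, against 0 on the others. In the after-calving group replicate 4 stood apart for S100A12 at -0.25 (others 5.06 to 5.52) and S100A4 at -4.09 (others 0.27 to 0.75), both as scaled log2 signal.

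The processed signal of before-calving replicate 3 correlated at 0.489 to 0.709 with the other 5 brighter arrays. The surface correction of the extraction software is a candidate cause. With the background-subtracted signal, which lacks it, the lowest correlation was 0.774, above the lowest among the other 5 arrays (0.688), as that explanation needs. No biological explanation was tested, as the labels set this array apart in nothing.

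The granule protein list was higher after calving on the 6 brighter arrays. A larger share of neutrophils after calving would raise other neutrophil genes alike. The gap between the granule list and the adhesion genes above the floor on all arrays (ITGB2 and CXCR1) widened by 2.32 (SE 0.28). These 2 genes therefore did not rise with the list. ITGB2 is expressed by other leukocytes too, which leaves CXCR1 alone (-1.27, adjusted p by limma 0.0629). A single gene cannot decide, so a larger share of neutrophils stays open. Slide and scan cannot be told apart from time, as 0 slides hold both. A change in the neutrophils around calving stays open and untested.

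Of 4 T cell markers 2 fell after calving on the same arrays. Fewer mononuclear cells of all kinds would lower B cell markers alike. The difference of the T cell mean lay below that of the B cell marker CD79A by a gap of -0.93 on the log2 scale (SE 0.60), which a single marker cannot decide, and CSF1R of monocytes was lower as well. Whether a smaller admixture of lymphocytes and monocytes underlies the lower T cell, class II and interferon values stays open. No test tied the class II or interferon genes to such admixture, and it cannot be told apart from slide and scan (0 slides hold both times).

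The 8 arrays split into 35 pairs of groups. The real count of 0 genes is met by all 35 whatever the data, so it tests nothing. At least the real count of 1 list of any kind came from 29 of 35 (highest other 2), so chance is not excluded for that count. The splits tested 449 to 1395 features, and 16 of them had enough members to test the class II list. In 1 of these 16, the real split, its p by camera was as low as the real value of 3.32e-05 (lowest other 0.121), and 16 splits are too few for a share under 0.05. The highest other split gave 17 genes, and 2 further splits gave 8 and 5. Each of these 3 set after-calving replicates 1 to 3 with 1 of the before-calving replicates 1 to 3 against the rest, which keeps both dim replicates numbered 4 on the same side. The split that exchanged after-calving replicate 4 for before-calving replicate 4 gave 0 genes. These splits therefore do not single out after-calving replicate 4. The 6 brighter arrays make 10 splits, too few for a share under 0.05. The real split gave 92 genes (highest other 0) and 4 lists (highest other 1), with 1 split of 10 as large in each.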

How the results depend on the processing

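The 6-array fit, its alternatives, the scaling over all probes and the 8-array fit with subtracted signal were chosen after seeing the data, and the cause was not tested where a count moved. The 8-array gene count was 0 in the other alternatives, and 1 with no filter on dim probes, 11 with array weights, 6 at an unadjusted p under 0.05 with 2-fold, 18 on the 6 brighter arrays with processed signal, 92 with subtracted signal, and 0 to 1 with each array left out. Its list count of 1 became 2 with normexp, 2 with quantile normalization, 4 with no filter, 2 with array weights, 3 and 4 on the 6 brighter arrays with processed and subtracted signal, 0 on 8 arrays with subtracted signal, 0 with an estimated correlation, 0 by fry, and 1 to 3 with each array left out. The 6-array gene count of 92 became 47 with normexp (45 higher, 2 lower), 5 with series matrix values, 2 with no filter, 44 with probes well above background on all arrays, 58 with trend and robust, 156 with array weights, 18 with processed signal, 7 with before-calving replicate 4 added, 244 at an unadjusted p with 2-fold, and 4 to 124 with each array left out. Scaling over all probes gave 89 (12 higher, 77 lower), each array's own floor 84 (46 higher, 38 lower) and quantile normalization 110 (44 higher, 66 lower). Its list count of 4 became 13 with no filter, 1 with probes well above background on all arrays, 0 with an estimated correlation, and 2 to 4 with each array left out. With before-calving replicate 4 added, which also raises the common floor, it was also 4, but 3 higher and 1 lower with 2 lists in common. Glycolysis and ribosomal proteins were then called higher, heat shock no longer passed (adjusted p = 0.0724) and the interferon list could not be tested. With normexp the list count was 4 with 3 lists in common, as ribosomal proteins were called lower than the other features by camera and the interferon list no longer passed (adjusted p = 0.414). Pathogen recognition was called higher with processed signal and before-calving replicates 1 and 2 only (adjusted p = 0.0303). By camera, against the other features, the granule list was higher in all 24 alternatives (past the threshold in 23) and the class II list lower in all 24 (23), with the heat shock list lower in 25 (18) and the interferon list lower in 23 (18). On balance by fry the direction was not always the same. By fry the interferon list was higher with normexp (adjusted p = 0.657) and the heat shock list with series matrix values (adjusted p = 0.806), neither past the threshold. All alternatives but 1 kept the preset correlation, and with the estimated correlation none of the 4 lists passed. The random block entered the gene fit alone. Its list tests were those of the main fit by construction, so it adds nothing to the list counts in which it is included. With probes well above background on all 6 arrays the granule, class II and interferon lists could not be tested. SERPINB4 stayed past the threshold in 21 of 22 alternatives, LTF in 18 of 22, ALOX15 in 18 of 23, PGLYRP1 in 13 of 22, IFI30 in 13 of 23, GNLY in 11 of 21, CSF1R in 11 of 23, LITAF in 10 of 23, HSPA8 in 4 of 23, ZFP36L2 in 5 of 22 and FAS in 6 of 21. The lowest value over the alternatives was 1.62 for SERPINB4, 0.59 for LTF, 0.74 for HP and 0.50 for ALPL. In the 6-array fit these genes lay at the common floor on all arrays before calving, and adding before-calving replicate 4 raises that floor. The median of all features on 6 arrays was -0.07, and moved to 0.66 with normexp, 1.02 in the series matrix, -0.58 with scaling over all probes, -0.25 with quantile normalization, and -0.33 with processed signal and before-calving replicates 1 and 2 only. Same-numbered arrays did not all deviate together (residual correlations 0.58, 0.22, -0.29 and 0.46 on 8 arrays, 0.09, -0.26 and 0.26 on 6), and not every array correlated best with its own number, although before-calving replicates 1 and 4 did on 8 arrays, so the numbers were not taken as pairs. With the replicate block the count was 0 on 8 arrays and 0 on 6, with 1 and 4 lists. Slide and scan as blocks were not run, because no slide or scan holds both times. Lists were not tested with probes well above background on all 8 arrays, which left too few members. Low signal over background limits which genes could be tested.

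Of 531 values of the 23 genes named on 8 arrays under the alternatives, 487 kept their direction and side of the threshold, 10 passed it in addition and 34 changed sign. Of 1345 values of the 61 genes named on 6 arrays, 1048 kept both, 205 no longer passed, 39 passed in addition and 53 changed sign. A further 11 values had both times at the floor and no direction. On 8 arrays the changed signs were with normexp ITGB2 -0.51 and ANXA1 -0.021, with quantile normalization HSPB1 -0.64, with the median ANXA1 -0.053, HSPB1 -0.15 and NKG7 -0.14, with the series matrix GPX1 0.062 and NKG7 -1.56, with flagged spots kept NKG7 -1.90, with the replicate block NKG7 -0.19, with array weights GPX1 0.73 and NKG7 -0.96, with scaling over all probes GPX1 0.059, on 6 arrays with processed signal NKG7 -0.49, with subtracted signal ITGB2 -0.24 and NKG7 -0.56, and on 8 arrays with subtracted signal ITGB2 -0.88, ANXA1 -0.35 and HSPB1 -0.017. With each array left out the ranges were ANXA1 -0.60 to 0.78, ATP5F1A -1.35 to 0.0062, COX6A1 -1.17 to 0.050, GPX1 -0.96 to 0.66, HSPB1 -0.36 to 0.66, ITGB2 -1.18 to 1.26 and NKG7 -1.04 to 1.19.

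On the 6 arrays the changed signs were with normexp SELPLG 0.85, IL1B 0.0077, GLRX 0.64, XAF1 0.26, DUSP1 0.41, BIRC3 0.14, FAS 0.18, TPI1 0.41, UQCRB 0.51, HADHA 0.48, LAMP2 0.60, CD79A 0.021, NKG7 0.39, CEBPE 0.63 and CXCR2 0.67. With series matrix values they were CXCR1 0.71, SELPLG 2.04, NFKBIA 0.13, IL1B 0.85, GLRX 0.30, ZFP36L2 0.63, DUSP1 0.99, BNIP3L 0.98, TPI1 0.85, UQCRB 0.89, ATP5F1A 0.53, HADHA 0.49, RPS15A 0.86, ATF4 0.0088, KLF6 0.25, FOSB 0.54, LYN 0.56, S100A4 0.28, CD79A 1.21, NKG7 0.52, CSF1R 0.018, CEBPE 0.80 and CXCR2 0.58. With scaling over all probes they were MCL1 -0.22, ACADVL -0.13 and TBXAS1 -0.29, with array weights MCL1 -0.41 and CD79A 0.016, with each array's own floor SELPLG 0.31 and CXCR2 0.13, with the mean of probes RPS15A 0.24, with processed signal SELPLG 1.02 and CD79A 0.19, and with before-calving replicate 4 added MCL1 -0.11. With each array left out the ranges were ACADVL -0.035 to 0.82, CXCR2 -0.15 to 0.073, MCL1 -0.82 to 1.04 and RAC1 -0.14 to 0.99.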

Other observations

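The genes in this part were chosen after their values were seen, among the 92 features past the threshold on the 6 brighter arrays. B2M, the light chain of class I histocompatibility molecules, fell by 1.98 (SE 0.18), and BOLA-DQB1, a class II gene outside the fixed list, by 1.95 (SE 0.29). CD163L1, of a family that marks gamma delta T cells in cattle, fell at least 4.01-fold (log2 -2.00) and GATA3, a transcription factor of T cells, at least 3.05-fold (log2 -1.61). RETN, which codes for resistin, rose by 1.73 (SE 0.18), though its other probe was at 0.03, and TCN1, a vitamin B12 binder stored in neutrophil granules, rose by 1.66 (SE 0.28). DEFB7, a beta-defensin, rose by 1.69 (SE 0.23).

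In 6 probes the signal was over 1000 on 1 array and not well above background on the other 7. The brightest were a transcript without a symbol on after-calving replicate 2, at 780549 against at most 9.81 elsewhere, and another on before-calving replicate 4, at 374030 against at most 10.2. FARS2 (2130), NCAM1 (1835) and ALG14 (1835) did so on before-calving replicate 4, and ERP44 (1920) on after-calving replicate 3.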
